A study of Mus musculus with 4 samples.

How the data were processed

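Livers of C57BL/6J mice were dissociated with enzymes, passed through a 40 µm strainer, pooled across animals within a group and fixed before library preparation with a probe kit for the mouse transcriptome, per the labels' protocols. The 4 libraries fell into 3 groups: STD (18% of energy from fat, 4 mice), CDHFD (45% of energy from fat, 3 mice) and CDHFD_SEMA (the CDHFD diet with semaglutide; replicate 1 from 4 mice, replicate 2 from 2 mice). Semaglutide was injected under the skin daily at 10 µg/kg in week 1, 20 µg/kg in week 2 and 40 µg/kg afterwards, with the last injection 2 h before collection. Sequencing depth in reads is not given in the sources used here.

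The deposited matrices hold UMI counts per gene and barcode, not normalized, which the authors made with Cell Ranger (version not given in the sources used here) on mm10, per the submitters' processing notes. Those notes also name R 4.5.0 and Seurat 5.3.0, whose output was not analysed here. The values were checked to be whole numbers, with the same gene list in all 4 libraries. The STD barcode sequences were not used, and 5 barcode lines of CDHFD_SEMA replicate 2 were blank, so cells were followed by column number. Gene positions were taken from the GENCODE vM21 annotation of mm10, matched by Ensembl ID for 99.94% of the listed IDs. The gene list of the files held no entry for Ly6c1, Cx3cr1, Nos3, Mx1, Xist and some other members of the lists, and these were left out.

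A barcode was kept with at least 500 UMIs, at least 300 genes and at most 10% mitochondrial UMIs. Of 47594 barcodes, 211 in STD, 82 in CDHFD, 98 in CDHFD_SEMA replicate 1 and 104 in replicate 2 had too few genes, and 355, 162, 470 and 239 too many mitochondrial UMIs. Doublets were scored per library by scrublet, as part of scanpy 1.11.5, and barcodes with a score above 0.2 were removed: 374, 278, 478 and 440. Scrublet's own thresholds called 339, 0, 564 and 600, so 1 threshold for all libraries was set after this was seen. The 44393 cells kept were clustered together without integration: counts scaled per cell and log-transformed, 2000 variable genes without mitochondrial and sex-linked ones, 40 principal components, 20 nearest neighbours, a graph weighted by shared neighbours and Leiden clustering (leidenalg 0.10.2) at resolution 1 with seed 1.

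Clusters were named from marker lists: the type with the highest mean log2 fold over the other cells, counting only markers detected in at least 20% of the cluster's cells. A cluster stayed unnamed with fewer than 3 markers above a log2 fold of 1, with its leading genes peaking in another class, or with low UMIs and no own marker among its first 10 genes. The naming rule went through 3 versions after the clusters were seen and before any comparison between libraries. Clusters 1, 11, 12, 20, 40 and 43 remained without a name; cluster 1 carried hepatocyte transcripts at a median of 919 UMIs. The endothelial class joined sinusoidal and vascular endothelial-like clusters, the macrophage class Kupffer-like and monocyte or monocyte-derived macrophage-like clusters, and the hepatocyte and stellate classes held 1 type each.

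Cells are not replicates, so UMIs were summed per library and class. For semaglutide against CDHFD, all 4 libraries were fitted with edgeR 4.0.16 (R 4.3.3; TMM scaling, filterByExpr, quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). The fit has 1 residual degree of freedom, from the CDHFD_SEMA pair, and takes the single CDHFD library to vary like that pair; the SE is the log2 change over the square root of the F statistic. CDHFD and STD had 1 library each, and no test of the diet was made: genes with at least 50 UMIs in 1 of the libraries were counted past a TMM-scaled log2 ratio of 1 with a prior count of 0.5, beside the number past that size between the CDHFD_SEMA libraries. Intervals of ratios and counts are exact at 95% and cover counting error only; where a library had 0 UMIs, the fold is a bound against a floor of 3 counts in that library. Genes at least 10 times higher in another class were counted apart, since free RNA or mixed cells can bring them. Shares of cells with a Glp1r UMI were also taken after thinning each cell to 2000 UMIs.

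The 29 gene lists, in 38 pairs of list and class, the tests, the filters and most alternatives were chosen before the data were examined. Each list gave a median log2 ratio over its measured members, compared with 10000 random lists drawn from the 100 nearest genes in expression. Counts adjusted over the list alone use that list's members only, without correction over the 38 pairs. By edgeR, 4404 of 13158 endothelial, 3016 of 10749 hepatocyte and 3377 of 12072 macrophage genes had an unadjusted p under 0.05. Such counts are therefore not particular to a list. Named genes were chosen by a rule: Glp1r always, from each list up to 4 members with the largest ratio in its class (for semaglutide on 1 side of CDHFD in both libraries), and in each class the 3 highest and the 3 lowest genes, without those at least 10 times higher elsewhere. A gene named in 1 comparison could be given in the other, and Hsd3b5 with semaglutide and the cell groups in which single genes are followed were chosen after their values were seen. Some genes that the rule names are not reported here.

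The fit was tested on simulated counts with the means, library sizes and dispersions of the data (5 simulations per class, 200 changed genes each). It called 63.8% of 2-fold and 84.2% of 4-fold changes in endothelial cells, 14.4% and 63.4% in hepatocytes, 66.4% and 85.2% in macrophages, and 13.4% and 75.0% in stellate cells, none on the wrong side. Between 26.6 and 40.4 unchanged genes passed per simulation. Even if all 200 changed genes had been called, that is a larger share of false calls than the adjusted p threshold allows. In these simulations the adjusted p was therefore too low in every class. Genes past the test with semaglutide are to be read with this limit, above all those near the threshold. By the size used for the diet, 202.8 unchanged endothelial, 279.6 hepatocyte, 223.8 macrophage and 523.6 stellate genes passed. For the comparison of diet and semaglutide ratios, 100 simulations with no effect gave the correlation that the shared CDHFD library alone brings. On lists drawn at random, 7.50% of 200 fell outside the central 90% of the percentile scale.

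Alternatives were DESeq2 1.42.0 (its size factors in edgeR and its Wald test), scaling by total counts, no filter on low counts, at least 10 UMIs per gene, a log2 ratio of 2, doublets kept, at least 1000 UMIs per cell, Leiden resolution 2, genes dominated by another class left out, and each CDHFD_SEMA library left out. Leaving out cells over 100000 UMIs, the settings for single named genes and the other settings for counts past a log2 ratio of 1 with semaglutide were added after seeing the data. Cell types outside the 4 classes were compared only after seeing the data. Counts were handled with Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 and drawn with matplotlib 3.10.9.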

Results

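Livers of C57BL/6J mice were profiled by single-cell RNA sequencing of fixed cells, a method in which gene-specific probes stand in for the transcripts. The study held 3 groups. Mice on a standard diet (STD) gave 1 library pooled from 4 animals, and mice on a choline-deficient high-fat diet (CDHFD), a model of steatohepatitis, gave 1 library pooled from 3 animals. Mice on the same diet that received daily semaglutide, a long-acting agonist of the glucagon-like peptide-1 receptor (GLP-1R), gave 2 libraries, CDHFD_SEMA replicate 1 from 4 animals and replicate 2 from 2 animals. The libraries held 11359 barcodes and 106300187 UMIs (unique molecular identifiers) in STD and 11571 barcodes and 119738761 UMIs in CDHFD. The CDHFD_SEMA libraries held 12399 barcodes with 134405848 UMIs (replicate 1) and 12265 with 137864763 (replicate 2), and the median UMIs per barcode were 4719, 4914, 5273 and 5122 in that order of libraries. The median share of mitochondrial UMIs per barcode was 0.951% in STD and 0.405% in CDHFD, the lowest, against 0.758% and 0.621% in the CDHFD_SEMA libraries. After filtering, 44393 cells remained, 10443 in STD, 11073 in CDHFD, 11393 in CDHFD_SEMA replicate 1 and 11484 in replicate 2. The series title places the GLP-1R of the liver endothelium at the centre of the drug's benefit. The design asks which liver cells carry Glp1r, what the diet altered in each cell class, and what differed when semaglutide was given on top of the diet.

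The CDHFD library was rich in immune cells. Cells resembling monocytes or monocyte-derived macrophages made up 4.01% of STD cells (exact 95% interval 3.64 to 4.41) and 14.3% of CDHFD cells (13.6 to 14.9), against 4.92% and 5.63% in the CDHFD_SEMA libraries. Kupffer-like cells, the resident macrophages of the liver, were 0.680% in STD, 1.72% in CDHFD, 0.737% in CDHFD_SEMA replicate 1 and 0.958% in replicate 2. NK or innate lymphoid-like cells had shares of 3.73%, 8.15%, 3.22% and 3.68% in the same order, and conventional dendritic-like cells 3.64%, 8.61%, 2.72% and 3.53%. T-like cells were 10.2% in STD, 17.0% in CDHFD, 8.43% in replicate 1 and 15.6% in replicate 2, so the semaglutide pools lay on opposite sides of STD. Neutrophil-like cells ran the other way, with 10.4% in STD, 3.90% in CDHFD, and 22.9% and 13.3% with semaglutide, as did B-like cells (8.69%, 3.34%, 6.43% and 7.58%). Hepatocyte-like cells made up 6.78%, 2.15%, 5.82% and 3.54%. Endothelial-like cells (15.2%, 15.1%, 14.2% and 11.7%), stellate or fibroblast-like cells (4.01%, 3.47%, 3.29% and 3.27%) and cholangiocyte-like cells (5.31%, 7.27%, 5.48% and 5.36%) differed less. Each share comes from 1 pool, so no test was made; the intervals are Clopper-Pearson and cover counting error, while dissociation, the 40 µm strainer and fixation can set shares. Clusters without a name held 20.0% of STD cells, 10.8% of CDHFD cells, and 16.6% and 19.9% of the CDHFD_SEMA cells.

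**Figure D1:**
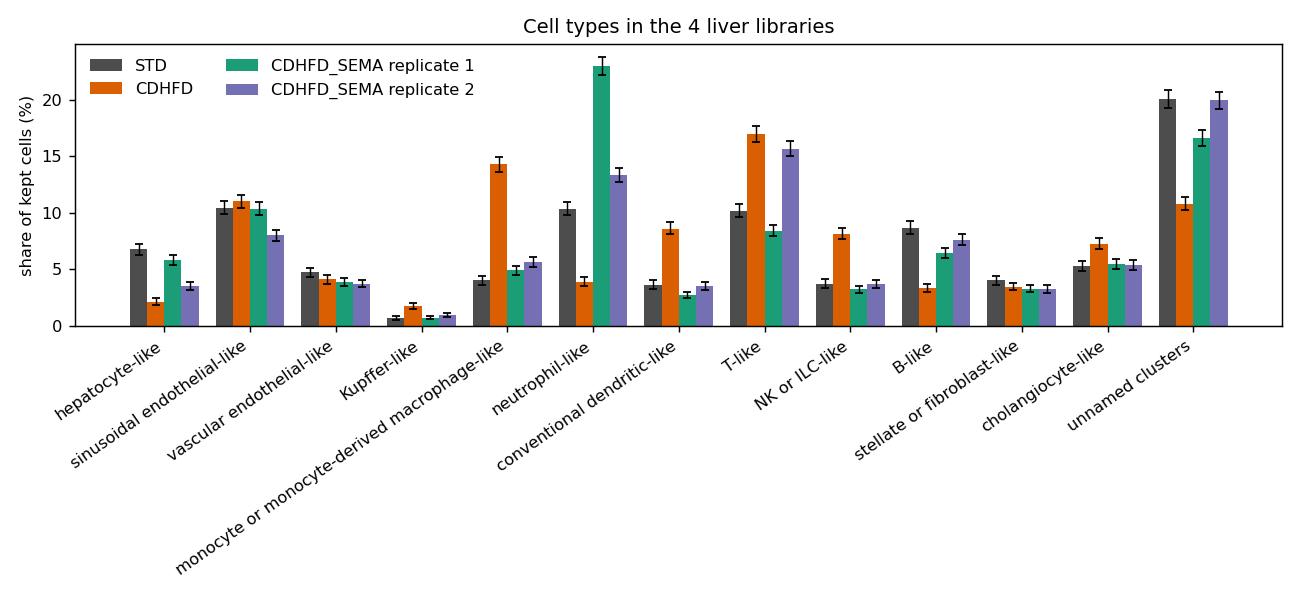
Share of kept cells (%, vertical axis) of each cell type (horizontal axis) in the 4 libraries; bars are shares and lines exact 95% binomial intervals for counting error. The monocyte or monocyte-derived macrophage-like bar stands at 14.3% in CDHFD and between 4.01% and 5.63% in the other 3 libraries.

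Glp1r (ENSMUSG00000024027, protein-coding, chromosome 17, 30901817 to 30940791, plus strand, mm10) was read mainly from venous endothelial cells. Of its 2776 UMIs in 44393 cells, 2084 (75.1%) lay in vascular endothelial-like cells, and 2081 of those in 1 cluster, cluster 10, which expressed Rspo3, Wnt9b, Selp and Vwf. Sinusoidal endothelial-like cells, 4405 in number, held 36 UMIs or 0.711 counts per 1000000 UMIs (CPM), against 75.1 CPM in the vascular cells. Hepatocyte-like cells held 2 Glp1r UMIs in 2015 cells. In cluster 10, Glp1r stood at 115 CPM in STD (Poisson interval 106 to 124), 84.8 in CDHFD (75.0 to 95.6), 86.3 in CDHFD_SEMA replicate 1 (79.2 to 94.0) and 108 in replicate 2 (99.8 to 117). The share of cluster 10 cells with a Glp1r UMI was 47.8% in STD and 33.5% in CDHFD, at median depths of 12370 and 7831 UMIs, and 42.5% and 49.7% in the CDHFD_SEMA libraries. Thinned to 2000 UMIs per cell, these shares were 19.6%, 15.0%, 15.2% and 16.0%, with 26, 36, 19 and 17 shallower cells left out. Neutrophil-like cells of the STD library, which should lack the receptor, had a UMI in 0.0923% of 1083 cells at a median depth of 4656 UMIs. Over the whole endothelial class, the CDHFD to STD log2 ratio was −0.94 (interval −1.15 to −0.74), and within cluster 10 it was −0.44 (−0.65 to −0.23). With semaglutide the class ratios to CDHFD were 0.47 and 0.93 (a mean of 0.21 with cells thinned to 2000 UMIs), and edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment gave a log2 change of 0.77 (SE 0.24, adjusted p = 0.095), short of the threshold. T-like cells held another 369 UMIs, 332 of them in cluster 9.

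**Figure D2:**
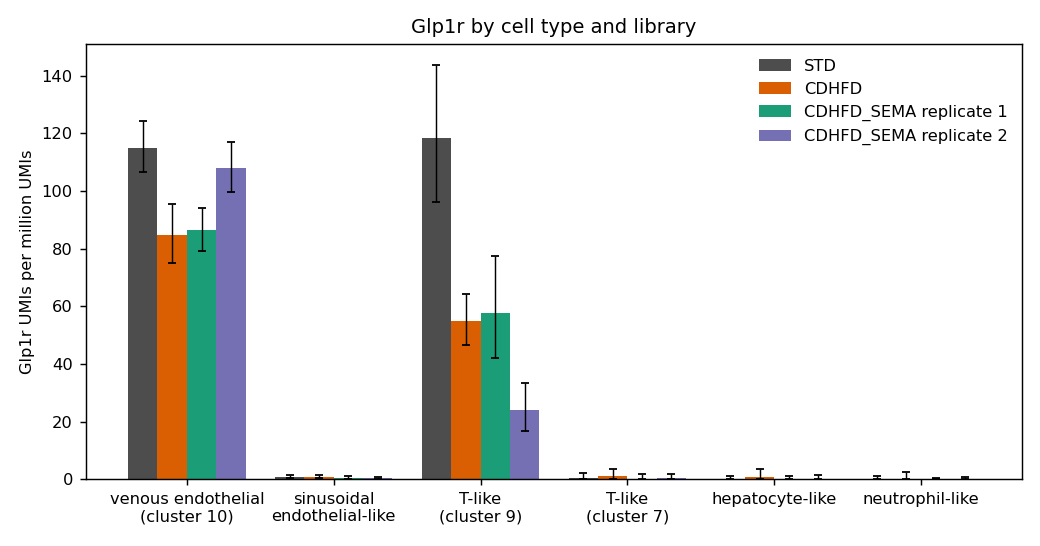
Glp1r CPM (vertical axis) by cell group (horizontal axis) in each of the 4 libraries; bars are values and lines Poisson 95% intervals. Cluster 10 stands between 84.8 and 115 CPM, the T-like cluster 9 between 24.1 and 118, and the sinusoidal cells below 1.

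In endothelial-like cells, the CDHFD library showed more interferon-stimulated and immediate early transcripts than STD, more of several leukocyte-recruiting ones, and fewer pericentral ones. All 17 measured interferon-stimulated genes lay above STD with a median log2 ratio of 1.44, 11 of them past a log2 ratio of 1. Isg15, a ubiquitin-like interferon effector (ENSMUSG00000035692, chromosome 4, 156199424 to 156200818), had a log2 ratio of 2.32 (2.26 to 2.37), and Ifit1 and Ifit2 had 2.57 and 2.25. Of 13 adhesion and recruitment genes, 5 passed that size and none lay at −1 or below (median 0.69): Cxcl9, a T cell chemokine (ENSMUSG00000029417, chromosome 5, 92321347 to 92328079), was 5.46-fold higher (log2 2.45, 2.40 to 2.50), and Cxcl10 and Ackr1 both had 1.41. Of 10 pericentral endothelial genes 3 lay below −1 (median −0.72): Rspo3, a Wnt-enhancing signal to pericentral hepatocytes (ENSMUSG00000019880, chromosome 10, 29452416 to 29535867), at −1.54 (−1.59 to −1.49), Wnt9b at −1.16 and Kit at −1.15. Periportal genes were higher in 9 of 10 (median 0.34), led by Efnb2 at 1.17 and Ltbp4 at 0.90. Sinusoidal identity genes were slightly lower (median −0.23, 12 of 16 below STD), with Kdr at −0.97 and F8 at −0.79, but Lyve1, a hyaluronan receptor (ENSMUSG00000030787, chromosome 7, 110850607 to 110863239), at 1.54 (1.51 to 1.58). Capillarization and basement membrane genes had a median of 0.31 with 2 of 19 past the size, Esm1 (1.83) and Cd36 (1.28). Against 10000 random lists of like expression, the interferon-stimulated median lay above all, the pericentral median below all and the sinusoidal median at percentile 8.40; between the CDHFD_SEMA libraries the adhesion median was 0.76, larger than with the diet, and also lay above all.

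The cAMP response list, the pathway downstream of GLP-1R, had 10 of 17 members past the size in CDHFD (median 1.11). Of these 17, 7 were at least 10 times more abundant in another class, Nr4a1 (1.50) and Nr4a3 (1.97) among them, and 3 (Fos, Fosb and Dusp1) also stand in the immediate early and dissociation response list, whose median was 0.89 with 7 of 18 past the size; Fosb had 1.39, Egr1 1.39 and Atf3 1.25. The angiocrine list went both ways (median 0.10), with Angpt2 at 1.56 and Klf2 at 0.99. All 6 measured MHC class II genes were higher (median 1.30, Cd74 1.55), and all 6 were at least 10 times more abundant in another class, as were 6 of 12 proliferation genes (median 0.54). The largest ratios outside the lists were those of Glycam1 (10.57, interval 8.68 to 16.46, 1 UMI in STD), Csf3 (5.37) and Cfap69 (4.36), and at the lower end Rflna (−5.41, −7.92 to −4.05, 3 UMIs in CDHFD), Nqo1 (−3.29) and Cyp1a1 (−3.00). Without cells over 100000 UMIs, Glycam1 stood at 1.90, Csf3 at 2.88 and Ackr1 at 0.94. Across the class, 870 genes were higher and 303 lower by a log2 ratio of at least 1 among 11021 with at least 50 UMIs in 1 of the libraries, and 506 and 80 of them were at least 10 times more abundant in another class. The CDHFD_SEMA libraries differed from each other by that size in 296 genes. Each diet ratio compares 1 library with 1 library, with no replicate check.

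The interferon-stimulated and recruitment shifts were seen in both parts of the endothelium. The interferon-stimulated median was 1.33 in sinusoidal and 1.32 in vascular cells, and the adhesion median 1.23 and 0.44. The sinusoidal identity median was −0.46 in sinusoidal and −0.13 in vascular cells, and the capillarization median 0.46 and 0.26. The pericentral median was −0.35 and −0.58, but Rspo3 itself had −1.26 in vascular cells and −0.19 in sinusoidal cells, while Wnt9b had −0.82 and −1.63. At Leiden resolution 2 the sinusoidal cells divided: its cluster 0 held 957 cells in STD, 293 in CDHFD, and 1045 and 782 in CDHFD_SEMA, and its cluster 12, led by Esm1, Cxcl9 and Lyve1, held 122, 904, 117 and 134. The sinusoidal ratios were taken over all of these cells together.

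In hepatocyte-like cells, several genes of cholesterol synthesis, lipogenesis, lipid storage and stress were higher in CDHFD, and several genes of methionine and choline metabolism were lower. The median log2 ratio over 7208 genes was −0.26, so list medians are also given relative to it. Cholesterol synthesis genes had a median of 0.76 (1.02 relative), with 7 of 18 past the size upward and 2 downward. Lipogenesis genes had a median of 0.54 (0.80 relative, but 0.05 without cells over 100000 UMIs), 6 up and 1 down of 16: Fads2 had 1.93, Srebf1 1.62 and Me1, malic enzyme, −1.22. Lipid droplet genes had a median of 0.63 over 11 genes (0.89 relative), 5 of them at least 10 times more abundant in another class. Of 10 with enough UMIs in STD or CDHFD, 4 were past the size, led by Cidec, a droplet-fusion protein (ENSMUSG00000030278, chromosome 6, 113424634 to 113435760), at 2.94 (2.43 to 3.52). Among stress and injury genes 7 of 18 were past the size (median 0.68, 0.95 relative; 6 at least 10 times more abundant in another class), with the stress cytokine Gdf15 at 4.56 (4.10 to 5.10) and the cell cycle inhibitor Cdkn1a at 2.25. Of 14 methionine and choline genes 4 lay below −1 (median −0.71, −0.45 relative): Gnmt, a methyl group acceptor enzyme (ENSMUSG00000002769, chromosome 17, 46725664 to 46729168), had −2.27 (−2.32 to −2.23), Cth −2.14 and Bhmt, which uses choline-derived betaine, −1.65. Fatty acid oxidation genes were mixed, with 5 of 15 up, Acot2 at 2.73 and Pdk4 at 1.78, around a median of −0.49 (−0.23 relative). Against 10000 random lists of like expression, the lipogenesis median lay above all, but the methionine and choline median at percentile 29.4 and the oxidation median at 39.4, so other genes of like abundance were as low.

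Bile acid genes had a median of 0.69 (0.95 relative, but −0.07 without cells over 100000 UMIs) with 4 up and 2 down of 11; the transporter Abcc2 had 3.15, Abcc3 2.29 and Cyp7b1 −2.01. Acute phase genes split 3 up and 3 down of 15 around a median of −0.14 that was higher than for other genes (0.13 relative, percentile 98.8 of random lists, and 0.13 with scaling by total counts), with Saa1 at −2.35 (ENSMUSG00000074115, chromosome 7, 46740497 to 46742980), Saa2 at −2.26 and Hpx at 1.36. Gluconeogenesis genes had 1 of 9 past the size, Gls2 at −1.18 (list median −0.38, −0.11 relative), and drug metabolism cytochromes 2 of 7, Cyp2c54 at −2.53 and Cyp4a12a at −1.69 (list median 0.25, 0.52 relative). Interferon-stimulated genes had none of 6 past the size (list median over 14 genes 0.78, 1.04 relative, with Isg15 at 0.74). Proliferation genes (median 2.06, 2.33 relative) and immediate early genes (1.38, 1.64 relative) were for the most part at least 10 times more abundant elsewhere, 4 of 6 and 14 of 17. The highest genes were Ubd (6.65, 4.72 to 12.54, 1 UMI in STD) and Ifi27l2b (4.71, 3.31 to 7.24, 3 UMIs in STD). Hsd3b5 was at least 50.2-fold lower and Asns at least 14.0-fold lower, both with 0 UMIs in CDHFD against a floor of 3 counts, and Slco1a1 had −4.48 (−7.00 to −3.11, 3 UMIs in CDHFD). In all, 880 genes were higher and 1087 lower of 6680 (1164 and 538 with scaling by total counts), 482 and 19 of them at least 10 times more abundant elsewhere, and 363 genes differed between the CDHFD_SEMA libraries. Without cells over 100000 UMIs, 280 genes were higher and 518 lower of 6204. The CDHFD class rests on 238 cells, 5 of them over 100000 UMIs; without such cells the ratio was 0.13 for Scd1 (1.32 with them), 1.33 for Fads2, 0.91 for Pdk4, 0.58 for Cyp8b1 (1.67 with them) and −1.30 for Cyp2f2 (0.74 with them), against −1.59 for Gnmt, 3.19 for Cidec and 4.24 for Gdf15.

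In macrophage-like cells, the medians of the lipid-associated, inflammatory and MHC class II lists lay above STD in CDHFD and that of the Kupffer identity list below, with 8 of its 15 genes lower and 7 higher. Gpnmb, a glycoprotein of lipid-laden macrophages (ENSMUSG00000029816, chromosome 6, 49036546 to 49070929), had a log2 ratio of 1.86 (1.77 to 1.96), Cd63 1.54 and Trem2, a lipid-sensing receptor, 1.21; these 3 of 19 genes of the lipid-associated list passed the size (median 0.41). Of 19 inflammatory cytokine genes 8 were up and 2 down (median 0.65), with Nos2 at 1.45 (2.94 without cells over 100000 UMIs), Tnf at 1.37 and Ccl7 at −2.73. All 9 MHC class II genes were higher (median 0.85, 3 past the size), H2-DMb1 at 1.79 and H2-Ab1 at 1.03. Interferon-stimulated genes had a median of 0.80 with 4 of 17 past the size, Rsad2 at 1.34 and Isg15 at 1.11. Of 15 Kupffer identity genes 3 lay below −1 (median −0.57): the haemoglobin scavenger receptor Cd163 (ENSMUSG00000008845, chromosome 6, 124304656 to 124330527) had −2.31 (−2.39 to −2.22), Timd4 −1.27 and C6 −1.15. The Kupffer median lay below all 10000 random lists of like expression, the cytokine median above all and the lipid-associated median at percentile 99.4. Proliferation genes had a median of 2.07 with 10 of 16 past the size and 10 at least 10 times more abundant in another class, and the immediate early median was 0.03. Outside the lists, Sdc1 had 3.68 and Il12b, an interleukin-12 subunit, 3.65, while Ifna4 (−4.91), Cd209g (−4.31) and Cbr2 (−3.96) were lowest. In all, 579 genes were higher and 311 lower of 10779 (465 and 425 with scaling by total counts, which moved the median of all genes by −0.13), 331 and 149 of them at least 10 times more abundant elsewhere, with 158 between the CDHFD_SEMA libraries.

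The make-up of the macrophage class differed between libraries: cluster 8 held 130 of 490 STD cells, 1046 of 1771 CDHFD cells, and 160 of 644 and 199 of 756 CDHFD_SEMA cells. Within Kupffer-like cells (cluster 26) Cd163 had −2.19, and the Kupffer identity median was −0.48, against 1.18 in monocyte or monocyte-derived macrophage-like cells. Gpnmb had 5.96 in Kupffer-like cells and 0.82 within cluster 8, where the lipid-associated median was 0.19 and the cytokine median 0.40. The MHC class II median was 0.26 within cluster 8, 0.59 in Kupffer-like cells and 1.27 and 1.32 within clusters 16 and 19. The interferon-stimulated median was 0.59 within cluster 8, −0.02 in Kupffer-like cells and 0.26 and 1.19 within clusters 16 and 19.

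In stellate or fibroblast-like cells, quiescence-associated genes were higher in CDHFD, as were Col1a1 and Col3a1, while the matrix and activation list went both ways, with 16 genes above STD and 10 below. Col1a1 (ENSMUSG00000001506, chromosome 11, 94936224 to 94953042) had a log2 ratio of 1.03 (1.01 to 1.06), Timp1, an inhibitor of matrix proteases, 0.97 and Col3a1 0.86; the matrix and activation list had 2 of 26 past the size, Spp1 (2.46, at least 10 times more abundant in another class) being the other one, and a median of 0.13. Quiescent stellate genes had 4 of 17 past the size and 16 above STD (median 0.78), with Lrat, the retinol-storing enzyme, at 2.11, Colec10 at 1.54 and Ngfr at 1.30. Against random lists the quiescent median lay above all and the matrix median at percentile 92.6. Most CDHFD cells of the class came from cluster 23 (215 of 384, against 126 of 419 in STD), and within clusters 15 and 23 the quiescent median was 0.09 and 0.27, the matrix median 0.20 and 0.78, and Col1a1 stood at 0.94 and 2.93. Ubd (5.56, 3.98 to 8.94, 2 UMIs in STD), Cxcl9 (3.38) and Pdgfb (2.50) were highest, and Ptn (−2.57) and Wif1 (−2.51) among the lowest. Proliferation genes had a median of 0.69 (5 of 10 at least 10 times more abundant elsewhere) and immediate early genes 0.09. In all, 375 genes were higher and 319 lower of 10566, 252 and 121 of them at least 10 times more abundant elsewhere, and the CDHFD_SEMA libraries differed from each other in more, 716.

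T-like cells of the CDHFD library carried more exhaustion and cytotoxicity transcripts. All 14 measured genes of that list lay above STD (median 1.12, 8 past the size): the checkpoint receptor Havcr2 had 2.39 (2.11 to 2.69), Pdcd1 2.00 and Lag3 1.63. All 9 genes of the naive and memory list lay below STD (median −0.70), Lef1 at −0.97 among them. Cluster 9 held 927 of 1881 T-like cells in CDHFD, 181 of 1061 in STD, and 136 of 960 and 285 of 1797 with semaglutide. The part of this make-up in the list shifts was not tested. In counts over whole libraries, 7 measured genes that differ between the sexes had a median of −0.56, with Mup20 and Cyp4a12a, male-type hepatocyte genes, at −1.85 and −1.91 and the Y-linked Uty at −0.56. Hepatocyte-like cells were 6.78% of STD and 2.15% of CDHFD cells, which lowers such genes in whole libraries; within hepatocyte-like cells Mup20 had −1.49 and Cyp4a12a −1.69.

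Against CDHFD, the semaglutide libraries had fewer interferon-stimulated transcripts in endothelial-like cells and more of several pericentral ones. The pericentral medians were 0.40 and 0.48 over the class, 0.44 and 0.09 in sinusoidal cells and 0.27 and 0.18 in vascular cells. Within cluster 10 they were 0.15 and 0.25, against 0.10 and 0.08 for all genes there. Whether the make-up of the class carries part of the rise was not tested. In sinusoidal cells the sinusoidal identity medians were 0.49 and 0.46 and the capillarization medians −0.50 and −0.45. Of 17 interferon-stimulated genes 13 fell and none rose (16 fell adjusted over the list alone). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, Isg15 changed by −1.86 on the log2 scale (SE 0.23, adjusted p = 0.028) and Ifit2 by −1.79 (SE 0.16, adjusted p = 0.025). Of 13 adhesion and recruitment genes 2 fell, and 2 adjusted over the list alone; Cxcl9 changed by −2.12 (SE 0.22, edgeR adjusted p = 0.025), lower in both libraries (−2.43 and −1.97). Of 10 pericentral genes 4 rose and none fell (6 rose and 1 fell adjusted over the list alone): Rspo3 by 1.40 (SE 0.16, edgeR adjusted p = 0.026), Kit by 1.22, Wnt2 by 0.85 and Cdh13 by 0.77. Of the sinusoidal identity genes 1 of 16 rose, Kdr, the VEGF receptor (0.92, edgeR adjusted p = 0.0499, or 0.0536 with DESeq2 size factors), and 1 fell, Lyve1 (−1.48, SE 0.17, edgeR adjusted p = 0.026), with the same counts adjusted over the list alone. In the capillarization list 2 of 19 fell (3 adjusted over the list alone), the tip cell genes Esm1 (−2.31, SE 0.42; adjusted p = 0.121 by DESeq2) and Apln (−3.51, SE 0.55), and in the periportal list 1 of 10 fell, Efnb2 by −1.03 (4 adjusted over the list alone).

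In the cAMP response list 16 of 17 members lay below CDHFD in both semaglutide libraries (medians −0.92 and −0.50); 2 fell and none rose by edgeR (7 fell adjusted over the list alone). In the immediate early and dissociation response list 17 of 18 lay below CDHFD in both libraries (medians −1.09 and −0.62), and 3 fell, the same number adjusted over the list alone, among them Dnajb1 (−1.10, SE 0.13). In the angiocrine list 2 rose and 2 fell of 16 (4 and 6 adjusted over the list alone), Angpt2 among those that fell (−1.84, SE 0.26). In the proliferation list 1 of 12 fell (2 rose and 4 fell adjusted over the list alone), and none of the 6 MHC class II genes passed in either way (medians −1.94 and −0.87). The furthest tested genes were Rflna (4.36, SE 0.90, from 3 UMIs in CDHFD), Gpr1 (2.65) and Olfr1396 (2.37) among those that rose, and Csf3 (−6.06, SE 0.44; −3.22 without cells over 100000 UMIs), Ptk6 (−3.84) and Apln among those that fell. In all, 847 genes rose and 668 fell of 13158 tested by edgeR (675 and 727 with DESeq2 size factors, 356 and 412 by DESeq2, and 1162 and 1285 without genes dominated by another class), and 170 were higher and 497 lower by a log2 ratio of at least 1 in both libraries (1188 in all in replicate 1 alone and 911 in replicate 2 alone). The test has 1 residual degree of freedom, from the CDHFD_SEMA pair, and assumes that the single CDHFD library varied like that pair. In simulations of each class its adjusted p let through a larger share of unchanged genes than the threshold allows.

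In hepatocyte-like cells, Cidec, Acot2 and Pdk4 fell with semaglutide and Saa1, Saa2 and Lcn2 rose. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 12 genes rose and 28 fell of 10749 tested (93 and 91 with DESeq2 size factors), and the genes named next as risen or fallen all had an adjusted p of 0.043. In simulations with 200 changed genes, 26.6 unchanged hepatocyte genes passed on average. That is a larger share of false calls than the adjusted p threshold allows, so part of the 12 and 28 calls may be false. Cidec fell by 4.83 on the log2 scale (SE 0.29; 1 of 11 lipid droplet genes fell, 4 adjusted over the list alone), and Acot2 by 3.01 and Pdk4, a switch from glucose to fat oxidation, by 3.35 (2 of 15 oxidation genes fell; 4 rose and 4 fell adjusted over the list alone, and the list medians were 0.25 and 0.39, or 0.02 and 0.16 relative to all genes). Saa1 rose by 4.25 (SE 0.34), Saa2 by 4.01 (SE 0.30) and Lcn2 by 2.12 (3 of 15 acute phase genes rose, 8 adjusted over the list alone). Cyp8b1, a bile acid 12-alpha-hydroxylase, fell by 2.78 (1 of 11 bile acid genes; 1 rose and 4 fell adjusted over the list alone), Gstm3 by 2.14 (1 of 18 stress genes; 2 rose and 10 fell adjusted over the list alone) and Cyp3a11 by 3.07 (1 of 9 cytochromes; 2 rose and 1 fell adjusted over the list alone). Mt2, a metallothionein, rose by 4.12 (SE 0.32) and Spon2 fell by 3.50 (SE 0.30). Among the 15 acute phase genes, 2 were at least 10 times more abundant in another class. Whether RNA of other cells brings part of that list's rise was not tested. Of 6 proliferation genes 2 fell, Ccnb2 and Stmn1 (3 adjusted over the list alone), both at least 10 times more abundant in another class.

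Other lists passed only when adjusted over the list alone. Of all 10749 tested genes 3016 had an unadjusted p under 0.05 by edgeR, so such counts are not particular to a list. Methionine and choline genes had 6 of 14 rise there and none over all genes, with medians of 0.63 and 0.69 (0.40 and 0.46 relative to the median of all genes, 0.23 in both libraries); Gnmt had 1.76 and 1.89, and the list median lay at percentiles 84.1 and 77.3 of random lists of like expression. Cholesterol synthesis genes had 8 of 18 fall there and none over all genes (medians −1.22 and −0.62, or −1.46 and −0.85 relative). Lipogenesis genes had 1 rise and 5 fall of 16 there, with Scd1 at −1.26 and −1.18 (−0.16 for the fitted change without cells over 100000 UMIs). Gluconeogenesis genes had 1 of 10 fall there, and immediate early genes 1 rise and 8 fall of 17. None of 14 interferon-stimulated genes passed either way; Ifit3 had 3.38 in replicate 1 and 0.18 in replicate 2. Hsd3b5 was at least 38.8-fold higher in replicate 1 and at least 12.8-fold higher in replicate 2 than in CDHFD, where it had 0 UMIs, and Gdf15 had −2.61 and −3.75. By a log2 ratio of at least 1 in both libraries, 611 genes were higher and 345 lower (235 and 561 with scaling by total counts, 358 and 183 without cells over 100000 UMIs). In replicate 1 alone 1520 passed that size in all, and in replicate 2 alone 1442. The count of the test depended on single cells: without cells over 100000 UMIs 916 genes passed edgeR, and with called doublets kept 0 did (2795 at an unadjusted p under 0.05), against 178 by DESeq2. It also moved with the genes entered, to 1223 without genes dominated by another class and 2370 without the filter on low counts.

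In macrophage-like cells, some genes of the lipid-associated and inflammatory lists fell with semaglutide and several Kupffer identity genes rose. Of 19 lipid-associated genes 4 fell and none rose (5 adjusted over the list alone): Gpnmb by −1.43 (SE 0.11, adjusted p = 0.016 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), Cd63 and Trem2 both by −1.03, and Apoe by −0.96. Of 20 inflammatory cytokine genes 8 fell and 2 rose (14 and 2 adjusted over the list alone), Nos2 by −1.85 (SE 0.19) and Tnf by −1.65 (SE 0.25, edgeR adjusted p = 0.033). Of 15 Kupffer identity genes 6 rose and 2 fell (7 and 2 adjusted over the list alone): Cd163 by 2.07 (SE 0.22, edgeR adjusted p = 0.022), C6 by 1.41, Vsig4 by 1.22 and Clec4f by 1.12. Of 17 interferon-stimulated genes 4 fell and 1 rose (6 and 3 adjusted over the list alone), Rsad2 by −1.34 and Isg15 by −0.98. None of 9 MHC class II genes passed over all genes (7 fell adjusted over the list alone; medians −0.91 and −0.61, H2-Ab1 −1.17 and −0.77), and of 16 proliferation genes 3 fell (4 adjusted over the list alone), Tk1 by −0.95 (adjusted p = 0.174 by DESeq2). None of 18 immediate early genes passed, in either adjustment. Fcnb rose by 3.73 and Plppr3 by 3.30, while Mgarp (−2.49), Tmem171 (−2.32) and Slc6a8 (−2.27) fell furthest. In all, 498 genes rose and 349 fell of 12072 tested (233 and 188 by DESeq2, 947 and 834 without genes dominated by another class, 907 and 828 without cells over 100000 UMIs), and 167 were higher and 197 lower by a log2 ratio of at least 1 in both libraries (227 and 141 with scaling by total counts; 737 in all in replicate 1 alone and 658 in replicate 2 alone).

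Part of this class difference was also seen within cell groups. The MHC class II medians were −1.51 and −1.02 within cluster 16 but −0.03 and 0.01 within cluster 8. In Kupffer-like cells, Cd163 had 1.75 and 2.08, and by edgeR within that group rose with an adjusted p of 0.0075; C6 and Vsig4 rose as well (adjusted p = 0.029 and 0.030). Tnf was lower within clusters 16 and 19 as well. These fits within cell groups also rest on the single CDHFD library, and the simulations did not cover them. Within cluster 8, Gpnmb had −0.55 and −0.52 (edgeR adjusted p = 0.27), and the lipid-associated list had medians of 0.14 and 0.10, the opposite side of CDHFD from the class.

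In stellate or fibroblast-like cells no gene passed edgeR's quasi-likelihood test (0 of 13134; 1503 had an unadjusted p under 0.05, and DESeq2 called 29 up and 6 down). Quiescent stellate genes were lower in both libraries (medians −0.66 and −1.23, 14 of 17 below CDHFD in both; 3 fell adjusted over the list alone), with Lrat at −1.44 and −1.91 and Nes at −1.50 and −1.69. Within cluster 15 the quiescent medians were −0.01 in both libraries and within cluster 23 −0.50 and −0.20, and cluster 23 held 215 of 384 CDHFD cells against 128 and 67 of 375 CDHFD_SEMA cells. Over the class, matrix genes had medians of −0.32 and −0.20, none of 26 past either adjustment, with Col1a1 at −1.44 and −0.82 and Col3a1 at −1.35 and −1.09. The matrix medians were −0.96 and −0.67 within cluster 23 and −0.28 and −0.32 within cluster 15. Within cluster 15, which held 247 of 375 and 308 of 375 CDHFD_SEMA cells and 169 of 384 CDHFD cells, Col1a1 (−1.13 and −0.90) and Col3a1 fell by edgeR (adjusted p = 0.044 and 0.037). None of 10 proliferation or 18 immediate early genes passed either adjustment. Ptx3 (3.63 and 5.46), Apod (4.83 and 3.95) and Dlk1 (4.80 and 2.80) were highest and Saa3 (−3.40 and −6.30) and Nrep (−2.30 and −2.07) among the lowest. Ubd was at least 41.5-fold lower in replicate 1, with 0 UMIs, and had 3 UMIs in replicate 2. By a log2 ratio of at least 1 in both libraries, 206 genes were higher and 137 lower (623 in all in replicate 1 alone and 1020 in replicate 2 alone).

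In T-like cells, 11 of 14 exhaustion and cytotoxicity genes fell and none rose (13 fell adjusted over the list alone), while all 9 naive and memory genes rose under both adjustments. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, Pdcd1 changed by −2.16 (SE 0.11), Havcr2 by −2.31 and Lag3 by −1.90, against Lef1 by 0.98. Cluster 9, with Gzmk, Pdcd1 and Tox among its leading genes, held 927 cells in CDHFD, and 136 and 285 with semaglutide. Changes within T-like cells were not separated from this change in make-up. Of the 7 sex-linked or sex-biased genes in whole libraries 3 rose, under both adjustments, among them Mup20 (0.94) and Uty (0.63). The hepatocyte share was also higher than in CDHFD (5.82% and 3.54% against 2.15%), which raises hepatocyte genes in whole libraries; within hepatocyte-like cells Mup20 had 1.15 and 1.05 (edgeR adjusted p = 0.112).

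**Figure D3:**
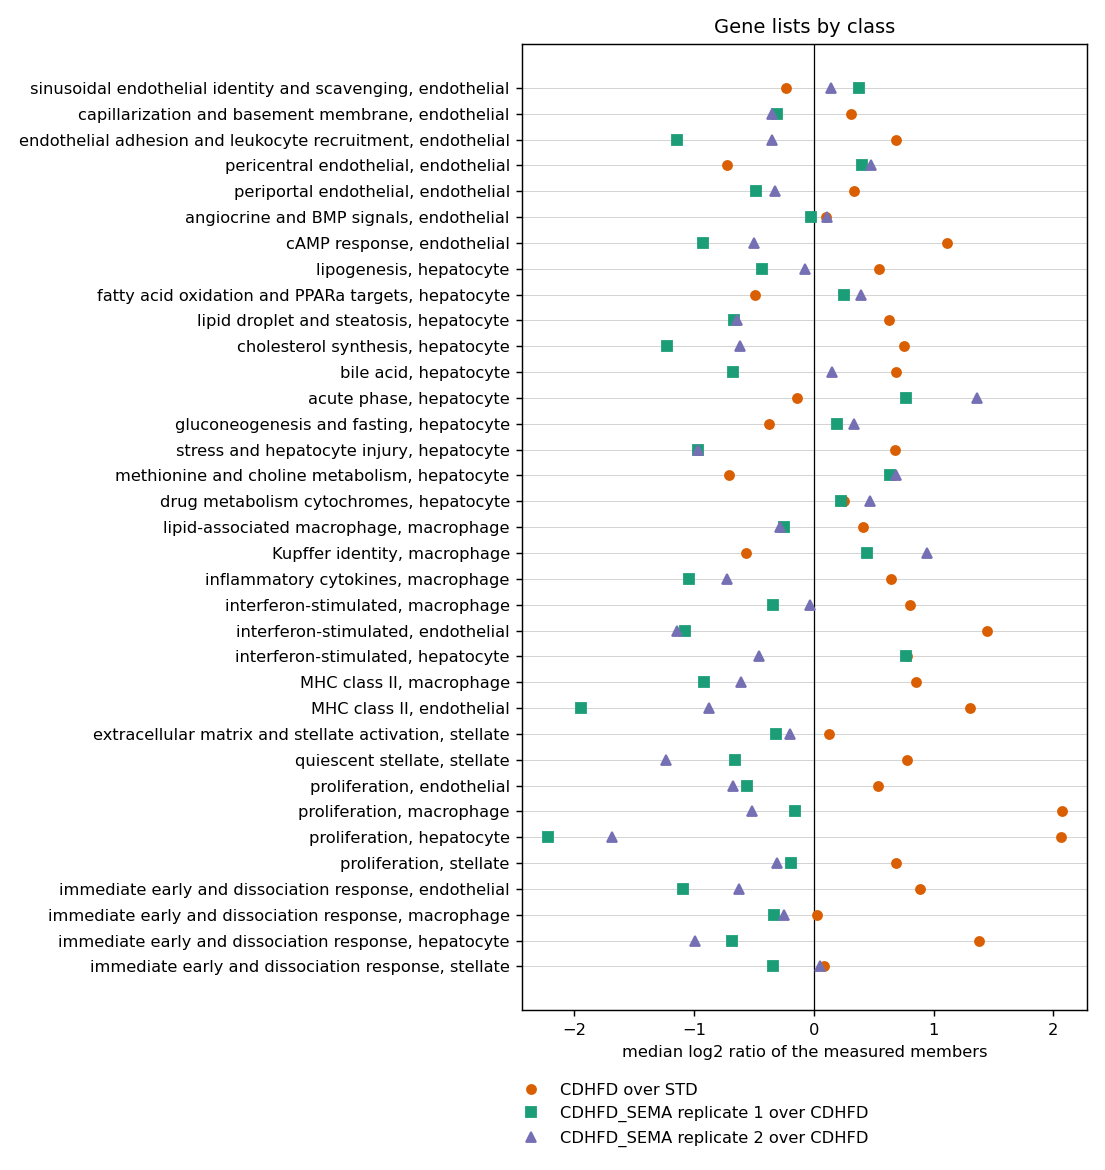
Median log2 ratio (horizontal axis) of each gene list in its cell class (vertical axis, 35 pairs) for CDHFD over STD and for each CDHFD_SEMA library over CDHFD; points are medians over the measured members. The interferon-stimulated list in endothelial cells stands at 1.44 for the diet and at −1.08 and −1.14 for semaglutide.

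Gene by gene, the semaglutide ratios ran opposite to the diet ratios. Of the genes past a log2 ratio of 1 between CDHFD and STD with at least 50 UMIs in any of the 4 libraries, 1144 of 1198 endothelial, 1934 of 2083 hepatocyte, 786 of 918 macrophage and 630 of 744 stellate genes lay on the other side of CDHFD in both semaglutide libraries, or 95.5%, 92.9%, 85.6% and 84.7%. Simulations with no effect, in which the shared CDHFD library alone gives opposite signs, had 77.7%, 82.8%, 67.1% and 76.2%. The correlation across genes, which are not independent replicates, was −0.896 in endothelial, −0.880 in hepatocyte, −0.714 in macrophage and −0.819 in stellate cells, against simulated means of −0.583, −0.601, −0.486 and −0.581. The covariance was −0.402, −0.732, −0.248 and −0.297, against −0.0643, −0.135, −0.0499 and −0.133 simulated, a difference of −0.337, −0.597, −0.199 and −0.164. Of the same diet-shifted genes, 89.9%, 87.9%, 71.0% and 82.7% stood within a log2 ratio of 1 of STD in the mean of the semaglutide libraries, against 76.2%, 82.1%, 63.7% and 74.1% simulated. Part of each excess may come from the shared CDHFD library, which cannot be split. A changed make-up of the classes may bring part as well, which was not tested.

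**Figure D4:**
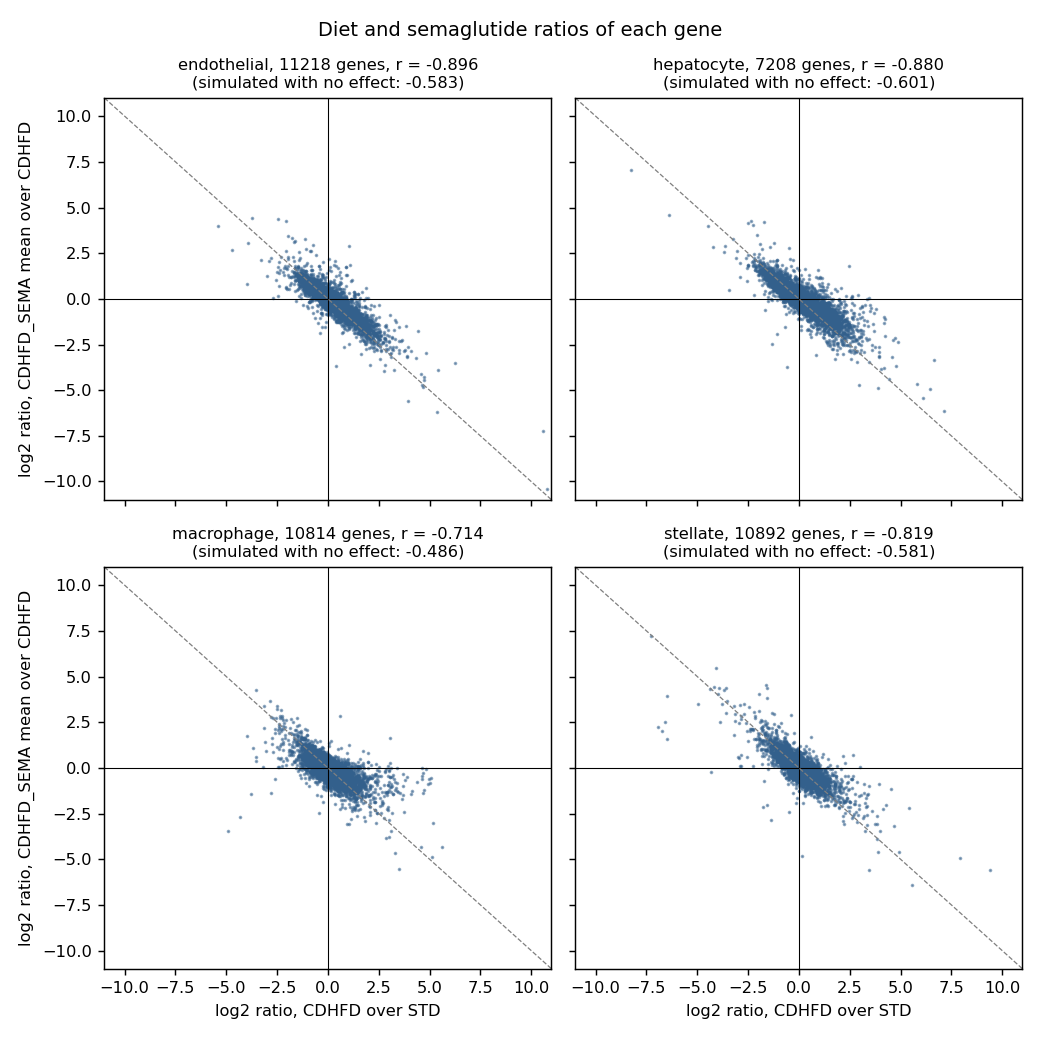
Log2 ratio of the mean of the CDHFD_SEMA libraries over CDHFD (vertical axis) against the log2 ratio of CDHFD over STD (horizontal axis) in the 4 cell classes; each point is a gene with at least 50 UMIs in 1 of the libraries and the dashed line marks equal and opposite ratios. The clouds follow the line, with r from −0.714 (macrophage) to −0.896 (endothelial).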

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

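The test against an even probe background and the comparison of cells with and without Glp1r were chosen only after the result was seen; the test with endothelial markers was set down before.

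T-like cells, a type outside the 4 classes compared, held 369 Glp1r UMIs (13.3% of all), a signal where no comparison looked for one. Of these, 332 lay in cluster 9, whose leading genes included Gzmk, Pdcd1 and Tox, at 118 CPM in STD, 55.0 in CDHFD, 57.8 in CDHFD_SEMA replicate 1 and 24.1 in replicate 2. After thinning to 2000 UMIs per cell, 17.4%, 9.25%, 9.68% and 3.23% of its cells had a Glp1r UMI, with 9, 127, 12 and 6 shallower cells left out. Cells of cluster 9 with Glp1r numbered 48, 112, 20 and 19, against 133, 815, 116 and 266 without. Among the genes furthest apart in a scan over genes, with no test, they had more Gzma in each library (log2 1.94, 1.52, 2.61 and 1.10), more Cd244a and more Lag3, and 0 Klrg1 UMIs, where the larger groups without held 37, 124, 49 and 122.

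Free RNA or doublets of venous endothelial cells would carry the 13 vascular endothelial markers along, but per Glp1r UMI cluster 9 held at most 6.12% of the marker UMIs of cluster 10 (1.12% in STD, 2.44% in CDHFD, 1.83% in CDHFD_SEMA replicate 1 and the maximum in replicate 2). An even background of the Glp1r probes would give other T-like cells a like level. Cluster 9, at 56.8 CPM over all libraries, stood 62.0-fold over the upper 95% limit of clusters 7 and 22, which held 5 UMIs in 2320 cells. That pair was among the lower T-like clusters. Cluster 42 stood at 9.92 CPM (18 UMIs), cluster 17 at 3.18 (12 UMIs), cluster 25 at 0.877 and cluster 32 at 0. The low marker share and these uneven levels argue against these sources. Binding of the probes to another transcript of this subset stays open, and no biological explanation was tested.

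Cluster 12, left without a name, stood out by its uneven spread: it held 943 cells in CDHFD_SEMA replicate 2 against 142 in STD, 116 in CDHFD and 100 in replicate 1, at a median of 1206 UMIs, with Duxf3, Flg and Vmn1r91 leading and 51 Glp1r UMIs (18.1 CPM).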

How the results depend on the processing

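Leaving out cells over 100000 UMIs, the settings for single named genes, and the settings other than single libraries for counts past a log2 ratio of 1 with semaglutide were chosen only after the results were seen. No paired analysis was possible because the groups share fewer than 2 replicate numbers, and no group had enough libraries to permute. STD and CDHFD without semaglutide had 1 pool each, so the spread between pools was measured for CDHFD_SEMA alone. In hepatocytes (238 CDHFD cells) and stellate cells the simulated test found 14.4% and 13.4% of 2-fold changes.

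Directions were largely kept. Of 280 list medians under settings planned beforehand, 205 moved by less than the gap between the CDHFD_SEMA libraries, 74 by more and 1 changed side; without cells over 100000 UMIs the numbers were 44, 24 and 2 of 70. The acute phase median with the diet was 0.13 by total counts and 0.0665 without cells over 100000 UMIs, and the bile acid median −0.0694 without them. Scaling by total counts moved the median of all hepatocyte genes by 0.26 with the diet and by −0.17 and −0.33 with semaglutide. Of the class shares, 60 of 66 under planned settings held within their error. With at least 1000 UMIs per cell the stellate share differed by −0.981 points with the diet and by 0.202 with semaglutide, the other way round, cholangiocytes by −1.999 with semaglutide and unnamed cells by −5.99 with the diet. Leiden resolution 2 gave stellate −0.669, kept doublets cholangiocytes 2.06 (both with the diet), and no cells over 100000 UMIs cholangiocytes −2.02 (semaglutide). The cause was not tested for these shifts. Genes named in the 4 classes kept their side of 0 where they had passed. Of 270 diet ratios, 226 moved by no more than the gene's gap between the CDHFD_SEMA libraries divided by the square root of 2. With semaglutide 167 of 184 kept their call and 14 passed only under another setting. Esm1 (DESeq2, −2.33), Tk1 (DESeq2, −0.96) and Kdr (DESeq2 size factors, 0.89) no longer passed.

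Counts of genes followed thresholds by construction. Past the size for the diet, at least 10 UMIs gave 1971 endothelial, 3571 hepatocyte, 1614 macrophage and 1425 stellate genes, and a log2 ratio of 2 gave 231, 272, 195 and 149. Without genes dominated by another class, 587 endothelial, 410 macrophage and 321 stellate genes passed. In hepatocytes, leaving out cells over 100000 UMIs gave 798 with the diet and 541 past a log2 ratio of 1 with semaglutide. With 1 CDHFD_SEMA library left out, the genes past a log2 ratio of 1 numbered 911 to 1188 (endothelial), 1442 to 1520 (hepatocyte), 658 to 737 (macrophage) and 623 to 1020 (stellate), since a single library then decides.

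The number of genes past edgeR's test with semaglutide also moved. In endothelial, hepatocyte, macrophage and stellate cells DESeq2 called 768, 178, 421 and 35, and no filter on low counts 3417, 2370, 2787 and 381. Without dominated genes 2447 endothelial, 1223 hepatocyte and 1781 macrophage genes passed. Without cells over 100000 UMIs the counts were 2500, 916 and 1735. In hepatocytes DESeq2 size factors gave 184, Leiden resolution 2 gave 101, and kept doublets gave 0 (2795 at an unadjusted p under 0.05 by edgeR). The cause of these shifts was not tested.

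Thinned to 2000 UMIs, Glp1r had a log2 ratio of 0.21 with semaglutide in endothelial cells, and −0.46 with the diet and 0.11 with semaglutide in vascular cells; kept doublets gave 0.27 there. The correlation of diet and semaglutide ratios was −0.745 in macrophages and −0.832 in stellate cells without dominated genes, and with 1 library left out −0.879 to −0.834 (endothelial), −0.841 to −0.819 (hepatocyte), −0.673 to −0.666 (macrophage) and −0.746 to −0.730 (stellate). The cause was not tested.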

Other observations

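The comparisons of cell types outside the 4 classes, the count of shared barcodes, the Glp1r values within cluster 10 and without cells over 100000 UMIs, and the comparison of cells with and without Glp1r were chosen only after the results were seen. The simulations and the setting without genes dominated by another class were planned, but what each should show for an explanation to hold was written after the results were seen.

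Cholangiocyte-like cells carried the interferon-stimulated shift as well. Of 17 such genes 16 lay above STD in CDHFD (median log2 ratio 1.08), and 16 lay below CDHFD in both CDHFD_SEMA libraries (medians −1.02 and −0.67); Ifit3 stood at 2.79 with the diet and fell by 2.05 with semaglutide (edgeR adjusted p = 0.043, lower in 2 of 2 libraries). Proliferation genes in these cells had medians of 1.23 with the diet and −0.89 and −1.32 with semaglutide. The interferon-stimulated median with the diet was 1.06 in stellate, 0.57 in smooth muscle, 0.49 in conventional dendritic, 0.41 in T-like, 0.39 in B-like, 0.31 in NK or innate lymphoid-like and 0.14 in neutrophil-like cells. With semaglutide it was not below CDHFD in both libraries in T-like (−0.02 and 0.19), B-like (0.12 and 0.49), neutrophil-like (0.23 and 0.41), conventional dendritic-like (0.14 and −0.05) and NK or innate lymphoid-like cells (0.81 and −0.02). The proliferation median with the diet was −0.41 in T-like, −0.21 in conventional dendritic-like and −0.48 in B-like cells, against 0.23 in NK or innate lymphoid-like (1.43 and 0.22 with semaglutide), 0.45 in neutrophil-like and 0.06 in smooth muscle-like cells. Dmbt1, an epithelial secreted protein, had 13857 UMIs in STD cholangiocyte-like cells, 46 in CDHFD, 946 in CDHFD_SEMA replicate 1 and 55423 in replicate 2; cells over 100000 UMIs held 68.9% of the UMIs of this type.

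In neutrophil-like cells, Camp had a log2 ratio of 4.48 with the diet, Ngp 3.38 and Ltf 3.01. These genes also differed between CDHFD_SEMA replicates 1 and 2. Camp stood there at 32.1 and 2.26 CPM, Ngp at 89.3 and 16.0 and Ltf at 64.3 and 29.6. Cluster 2, with Retnlg and Mmp8 among its leading genes, held 630 cells in STD, 82 in CDHFD, 1809 in CDHFD_SEMA replicate 1 and 1002 in replicate 2. Past a log2 ratio of 1, 174 neutrophil genes were higher and 572 lower with the diet, 66 and 513 of them not at least 10 times more abundant in another class, and edgeR called 1678 up and 1218 down with semaglutide of 11154 tested. T-like cells had 820 up and 867 down, conventional dendritic-like cells 284 and 252, B-like cells 33 and 42, cholangiocyte-like cells 656 and 259, and NK or innate lymphoid-like cells 3 and 0. Smooth muscle-like cells had 0 past edgeR's test (1438 of 12220 at an unadjusted p under 0.05; no other tool was run there). Ccl1, a chemokine, had 0 UMIs in STD T-like cells, 425 in CDHFD, 211 in CDHFD_SEMA replicate 1 and 5 in replicate 2. The mitochondrial transcript mt-Nd1 stood in T-like cells at 679 CPM in STD, 170 in CDHFD, and 638 and 406 with semaglutide, and in conventional dendritic-like cells had −1.93 with the diet, but mt-Nd6 in B-like cells had 1.49.

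In each of the 4 classes, gene shifts with semaglutide ran opposite to those with the diet. Chance error of the shared CDHFD library, of the size seen between the CDHFD_SEMA libraries, would leave the covariance among 100 simulations, but it lay below the lowest in every class, in stellate cells by the least, −0.164 from the simulated mean. RNA of other cell types was tested by leaving out genes at least 10 times higher elsewhere. The covariance still lay below all simulations, in stellate cells by the least, −0.0655 from the simulated mean. That difference shrank in the other classes too, from −0.3373 to −0.2313 (endothelial), −0.597 to −0.4055 (hepatocyte) and −0.1985 to −0.1335 (macrophage). Genes less than 10 times higher elsewhere stayed in, so the test cannot exclude such RNA as a part. A separate droplet run of the CDHFD library would leave few barcodes in common, but it shared 1873 and 1946 with the CDHFD_SEMA libraries, which shared 2176 with each other. An effect of semaglutide remains a hypothesis. A CDHFD pool further from its group than the CDHFD_SEMA pools are from each other stays open, since 1 library cannot show it. A changed make-up of the classes stays open too. Cluster 8 of the macrophage class held 1046 cells in CDHFD, against 130 in STD and 160 and 199 in CDHFD_SEMA. At Leiden resolution 2, sinusoidal cluster 12 held 904, against 122, 117 and 134. The part of make-up in the opposite shifts was not tested.

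The endothelial class held less Glp1r in CDHFD than in STD (log2 −0.94). Cells of very high UMI count do not make this difference, which was −0.85 without cells over 100000 UMIs. Cluster 10 held 2081 of the 2120 Glp1r UMIs of the class over all libraries. Within it the ratio was −0.44 (−0.65 to −0.23), smaller than in the class. In these libraries most of the rest of the class difference therefore lies in a smaller share of cluster 10 UMIs. Whether the level in the venous cells of cluster 10 was lower as well stays open. The CDHFD_SEMA libraries differed there by 0.32, too near to decide with 1 library per diet. With semaglutide the ratios within cluster 10 were 0.03 and 0.35.

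In cells of cluster 10 with a Glp1r UMI, the periportal list was lower than in those without, with medians of −0.83 in STD, −0.60 in CDHFD, −0.79 in CDHFD_SEMA replicate 1 and −0.83 in replicate 2, and the pericentral list higher (0.40, 0.03, 0.30 and 0.25). Among the genes furthest apart in a scan over genes, Cyp1b1 was higher by 2.00, 1.85, 1.66 and 2.03, and Stab2, a sinusoidal scavenger receptor, lower, at −4.05, −2.35, −2.24 and −2.58. Cells with Glp1r were deeper (median 16022 UMIs against 8885.5 in STD), which raises the chance of a UMI. At Leiden resolution 2, leading genes of cluster 10 headed a vascular endothelial-like cluster (19, 958 cells) and a sinusoidal endothelial-like one (33, 395 cells). Cluster 10 may thus be mixed, and whether that mix sets these differences was not tested.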
